A study of Ictalurus punctatus with 9 samples.

How the data were processed

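Skin RNA of channel catfish (Ictalurus punctatus) exposed to the bacterium Aeromonas hydrophila was compared with skin RNA of unexposed fish on 9 two-colour oligonucleotide arrays, 3 at each of 2, 8 and 12 h. Per the labels, fish were immersed for 2 h with the bacteria, 30 fish were held in each aquarium, and each array set 1 infected sample against 1 control sample. The labels call the 3 samples of a time biological replicates and do not say how many fish were pooled. The p-values measure the spread between these arrays.

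The scanner intensities were deposited as 1 file per array, made with Agilent Feature Extraction. The file headers give version 10.1.1.1 and the submitters' processing notes give 9.5.3. Per the file headers, the processed intensity columns were background-subtracted and dye-normalized by that software, and the LogRatio column holds the log10 ratio of red (Cy5) over green (Cy3). The flag columns that the authors deposited, a score of 0 or 1 per spot among other columns, mark spots well above background, saturated spots and outliers. The authors' value table holds a log10 ratio of infected over control. All 52649 of 52649 spots on each array equalled the LogRatio column to 5 decimals, with the sign turned on the 2 swapped arrays. Its column medians were 0 on 7 arrays, -0.0275 on replicate 1 of 12 h and -0.0569 on replicate 2 of 12 h. Per the labels, infected RNA was in Cy5 on 7 arrays and in Cy3 on replicate 3 of 2 h and replicate 3 of 12 h. No array of 8 h was swapped, so the 8 h estimate used the dye effect estimated from the other times.

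Mean signals and median local backgrounds were read with limma 3.58.1 in R 4.3.3, corrected by normexp with an offset of 50 and normalized by loess within each array. Control spots and outlier spots had weight 0, and outlier spots were then left out. Spots of 1 probe were averaged, which gave 50979 probes from 51330 spots, with 49375 different 60-base sequences. No spot was saturated. Probes were kept where both channels were well above background on all 3 arrays of at least 1 time, which left 9535. The fixed design had not stated this filter. It was chosen after the files were opened and before any test result was seen.

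Each probe's log2 ratio was fitted with limma to 1 infection effect per time and a dye effect over all 9 arrays. Calls have a Benjamini-Hochberg adjusted p under 0.05 from the moderated test (eBayes). The mean over the 3 times, the difference between times (F test) and each pair of times were contrasts of that fit. On simulated data with the real spread over 9535 probes, 52.2% of probes changed by 1 on the log2 scale were recovered at 2 h, 44.8% at 8 h and 61.2% at 12 h. Of probes changed by 2, 92.5%, 85.1% and 91.0% were recovered. False calls made up 5.26%, 5.59% and 7.18% of all calls. Each share of recovered probes rests on 67 probes in 1 draw. The simulated noise had the same spread at every time and left out the low infected signal of 12 h. The layout of 2 h and 12 h was the same, so the difference between them reflects the draw. These shares therefore do not measure the power at 12 h in the real data.

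The files do not pair probes with genes. Every description reads Unknown, the names are contig names, and 0 of the names matched the given gene table. The 33 gene lists fixed before the data were examined, the cell type markers and the set tests could therefore not be used. The naming rule fixed beforehand asked for named genes and passed over bare contig names. It was applied to probe identifiers instead, with 2 probes in each direction per time and the 4 probes of smallest p for the time difference. A named probe had an adjusted p under 0.05, the same sign on all 3 arrays of its time and the largest change. At 12 h none passed, and the probes of smallest p were taken instead.

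No pairing by replicate number was seen: 3 of the 9 pairs with the same number had a correlation of deviations over 0.1, against 8 of the 18 pairs with different numbers. The deviations within a time cancel out and hold the dye effect, so this check cannot show that the arrays were unpaired. The highest correlation, 0.34, joined the 2 swapped arrays, which also share a number. The arrays lay on 2 slides, 8 on the first and replicate 3 of 12 h alone on the second, so a term for the slide would absorb that array, as leaving it out does. Alternatives covered the dye term, background correction, normalization, dim-probe filter, spread model, array weights, thresholds, replicate block, separate channels, the authors' table and each array left out. The number of arrays limits the precision.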

Results

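The series asked how the skin of channel catfish responded within hours of exposure to Aeromonas hydrophila, a bacterium that infects fish through the skin and other mucosal surfaces. Infected and control skin were set against each other on 3 arrays at each of 2, 8 and 12 h. Control RNA gave 8213 to 26964 probes well above background per array and infected RNA gave 3819 to 15916. At 12 h, infected RNA labelled with Cy5 gave 4082 and 3819 such probes, and infected RNA labelled with Cy3 gave 14041. All changes are log2 ratios of infected over control skin from the limma fit, given with the standard error (SE), and the files do not pair probes with genes.

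**Figure D1:**
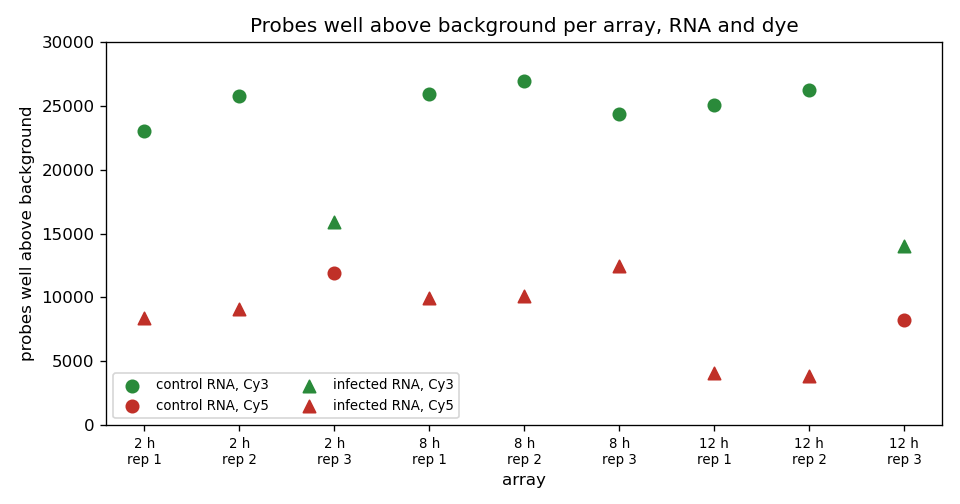
Probes well above background (y axis) on each of the 9 arrays (x axis) for control RNA (circles) and infected RNA (triangles), coloured by dye. On the 7 arrays with control RNA in Cy3, infected RNA gave 3819 to 12441 probes.

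At 2 h after exposure, 477 probes were higher and 561 were lower in infected skin, out of 9535 tested. Of these 1038 probes, 1000 had the same sign on all 3 arrays and 456 changed at least 2-fold. Probe CUST_44733_PI427014114 was lower by 23.8-fold, with a log2 ratio of -4.57 (SE 0.36, n = 3, limma adjusted p = 0.0019). Its sequence is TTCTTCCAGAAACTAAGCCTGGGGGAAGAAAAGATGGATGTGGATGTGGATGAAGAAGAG. Probe CUST_24223_PI427014114 was also lower, at -2.97 (SE 0.74, limma adjusted p = 0.039). Probe CUST_17310_PI427014114 was higher by 28.8-fold, at 4.85 (SE 0.86, limma adjusted p = 0.014), and probe CUST_33550_PI427014114 was higher at 3.50 (SE 0.80, limma adjusted p = 0.030). The call of CUST_33550_PI427014114 rested on 2 arrays, since its ratios were 5.62, 6.11 and 0.01. Infected signal of CUST_24223_PI427014114 was well above background on 2 of 3 arrays. The last 3 calls depended on the processing and on single arrays. CUST_17310_PI427014114 had ratios of 6.801, 7.004 and 2.314, and its effect was 4.66, 4.56 and 6.05 without replicate 1, 2 or 3 of 2 h. It had a limma adjusted p of 0.052, 0.10 and 0.098 without these and 0.099 with the robust and trended variance, and scaling between arrays put it at 0.14 (limma adjusted p = 0.998). CUST_24223_PI427014114 stood at -3.57, -2.28 and -3.22 and had 0.056, 0.20 and 0.28 without replicate 1, 2 or 3 of 2 h, 0.055 without replicate 1 of 8 h, 0.057 and 0.054 without replicate 2 or 3 of 12 h, 0.20 with scaling, 0.053 without background subtraction and 0.073 without the filter on dim probes. CUST_33550_PI427014114 stood at 3.06 and 2.81 without replicate 1 or 2 of 2 h (0.11 and 0.17) and at 6.30 without replicate 3 (1.3e-05). It had 0.054 and 0.053 without replicate 1 or 2 of 8 h, and 0.12 with scaling. It also had 0.069 with the replicate block, 0.081 from processed signals, 0.11 from the 3 arrays of 2 h alone, 0.054 without the filter on dim probes and 0.059 with median centring. Its effects there were 3.52, 4.09, 3.91, 3.50 and 2.11. Without replicate 3, the swapped array, 89 probes passed at 2 h, against 96 without replicate 2, 565 without replicate 1, and 625, 623 and 1588 without replicate 1, 2 or 3 of 8 h. With median centring in place of loess, the median of all probes moved to -0.96, and 0.63% of 2540 calls were higher against 46.0% with loess. Replicates 1 and 2 correlated at 0.81 across probes, and replicate 3 correlated with them at 0.19 and 0.39.

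At 8 h, 141 probes were higher and 75 were lower. Of these 216 probes, 214 had the same sign on all 3 arrays. Probe CUST_44733_PI427014114 was again lower, at -4.63 (SE 0.43, limma adjusted p = 0.0099). Probe CUST_45754_PI427014114 was lower at -2.50 (SE 0.38, limma adjusted p = 0.019). Probe CUST_35760_PI427014114 was higher by 13.1-fold, at 3.71 (SE 0.37, limma adjusted p = 0.0099), and has the sequence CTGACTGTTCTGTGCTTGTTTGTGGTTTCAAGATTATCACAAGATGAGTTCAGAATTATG. Probe CUST_15628_PI427014114 was higher at 3.56 (SE 0.43, limma adjusted p = 0.014). CUST_35760_PI427014114 and CUST_45754_PI427014114 had also passed at 2 h, at 2.83 and -1.77 (limma adjusted p of 0.0028 and 0.013), and CUST_15628_PI427014114 had not (0.81). Without replicate 1 of 8 h none of these 4 probes passed, with a limma adjusted p of 0.075 for 3 of them and 0.089 for CUST_45754_PI427014114. Their effects were then 3.83 for CUST_35760_PI427014114, 3.25 for CUST_15628_PI427014114, -4.67 for CUST_44733_PI427014114 and -2.52 for CUST_45754_PI427014114. Without replicate 2 of 8 h it was 0.052 for CUST_44733_PI427014114, 0.085 for CUST_15628_PI427014114 and 0.11 for CUST_45754_PI427014114, at -4.59, 3.25 and -2.51. Without replicate 3 of 8 h, CUST_15628_PI427014114 stood at 4.17 (limma adjusted p = 0.00059). CUST_45754_PI427014114 also had 0.053 and 0.054 without replicate 1 or 2 of 2 h and 0.051 without replicate 3 of 12 h, at -2.51, -2.46 and -2.58. It had 0.11 with the robust and trended variance, 0.091 with the replicate block and 0.068 from processed signals, at -2.50, -2.44 and -2.15. With median centring the limma adjusted p was 0.62 for each of the 4, and with scaling between arrays it was 0.093 to 0.26. The effects with median centring were 3.47 for CUST_35760_PI427014114, 2.57 for CUST_15628_PI427014114, -4.31 for CUST_44733_PI427014114 and -2.31 for CUST_45754_PI427014114. With scaling they were 2.42, 2.26, -2.81 and -1.29. No 8 h array was swapped: without the dye term 1285 probes passed, and 42.2% of these were higher against 65.3% with it. From processed signals 58 probes were higher and 5 lower (92.1% higher), and 0 passed with median centring or with scaling between arrays. Without replicate 1 of 8 h 0 probes passed and without replicate 2 there were 2, against 67 and 39 without replicate 1 or 2 of 2 h, and 70 and 103 without replicate 2 or 3 of 12 h.

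**Figure D2:**
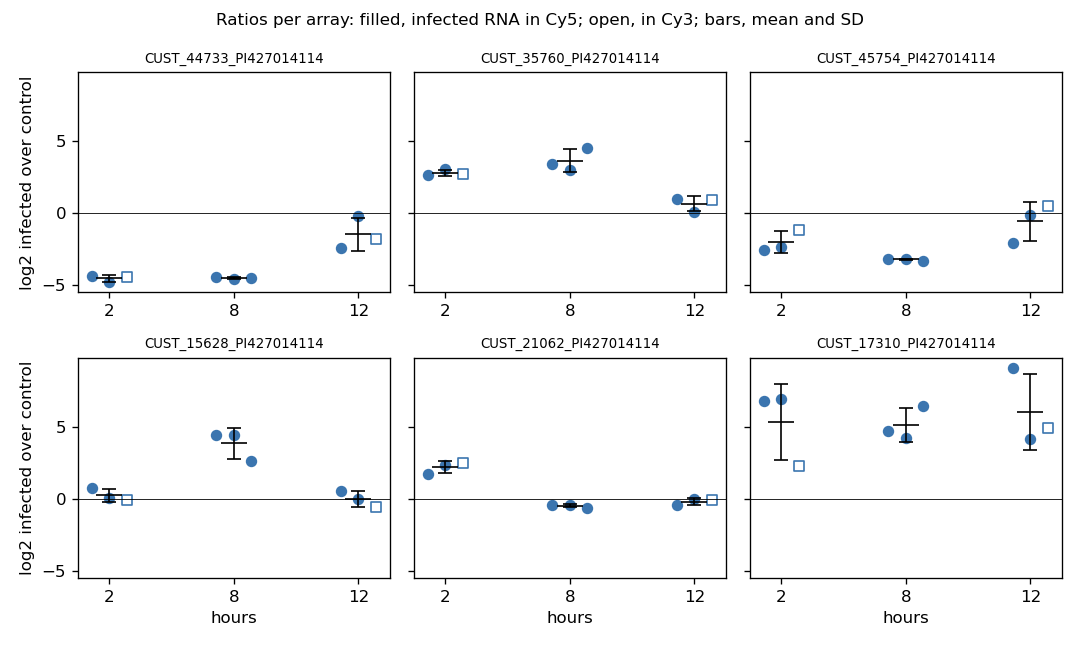
Log2 ratios of infected over control skin (y axis) of 6 named probes on each array by hours after exposure (x axis), with filled points for infected RNA in Cy5, open points for Cy3, and bars for the mean and SD of 3 arrays. CUST_44733_PI427014114 lay between -4.82 and -4.37 on all arrays of 2 and 8 h.

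At 12 h no probe passed with limma, and 815 of 9535 had an unadjusted p under 0.05. Only 3099 of the 9535 were well above background in both channels on all 3 arrays of 12 h. There were 7656 such probes at 2 h and 9053 at 8 h, so most probes tested at 12 h were not fully measured there. The smallest adjusted p was 0.093, for probe CUST_2634_PI427014114 at 2.68 (SE 0.29). Probe CUST_17488_PI427014114 stood at 3.68 (SE 0.48, limma adjusted p = 0.13), and had passed at 2 h, at 2.31 (limma adjusted p = 0.022). Without replicate 3 of 12 h, 140 probes passed, these 2 included at 3.59 and 5.05 (limma adjusted p of 0.00070 and 0.0023), and without replicate 3 of 2 h 40 passed, these 2 at 0.0025 and 0.0050. Without replicate 2 of 12 h, 2 probes passed. Both named probes also passed from processed signals, from unsubtracted signals, with separate channels and with array weights. They did not pass with median centring or scaling between arrays. Nor did they pass without the dye term (limma adjusted p of 0.67 each), from the 3 arrays of 12 h alone (0.90 each) or with the robust and trended variance (0.49 each). The replicate block gave 0.34 each, an offset of 16 gave 0.064 each, and no filter on dim probes gave 0.14 and 0.25. Among probes measured in both channels on all 9 arrays they had 0.053 and 0.066. Median centring put CUST_2634_PI427014114 at -1.49 and CUST_17488_PI427014114 at 0.27 (limma adjusted p of 0.071 and 0.71), and scaling put them at 25.9 and 30.4 (0.35 and 0.34). Their highest ratios on any array before scaling were 4.47 and 6.55, so scaling between arrays distorted the size of these effects. In the other direction, CUST_6182_PI427014114 stood at -0.84 (limma adjusted p = 0.25) and CUST_32450_PI427014114 at -0.79 (limma adjusted p = 0.34). The ratios of CUST_6182_PI427014114 were -0.015, -0.036 and -1.72, so only the swapped replicate 3 lay far below 0. Both of these lower probes passed from processed signals (0.020 and 0.011), from unsubtracted signals (0.028 each) and with median centring, at -3.91 and -2.95 (0.0048 each). With separate channels CUST_6182_PI427014114 passed (0.046) and CUST_32450_PI427014114 did not (0.16). In the main fit CUST_32450_PI427014114 had passed at 2 h and 8 h, at -1.84 and -1.74 (limma adjusted p of 0.0028 and 0.015). The ratios of replicate 3 did not follow those of the other 2 arrays, with correlations of -0.02 and -0.04 across probes. Replicates 1 and 2 correlated at 0.57. These ratios hold the dye effect, which turns sign on the swapped replicate 3. Replicate 2 lay near 0 for some probes that had passed at 2 h. CUST_44733_PI427014114 had -2.41, -0.19 and -1.82 on replicates 1, 2 and 3. CUST_35760_PI427014114 had 0.97, 0.06 and 0.92, and CUST_32450_PI427014114 had -0.74, -0.09 and -1.18. CUST_2634_PI427014114 and CUST_17488_PI427014114 stood at 4.47 and 5.18 on replicate 2. From Agilent's processed signals without loess 1974 probes passed at 12 h, with the median of all probes at -0.47, and from unsubtracted signals 352 passed.

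Over the mean of the 3 times, 242 probes were higher and 295 were lower (45.1% higher). The split depended on the scaling: 237 were higher and 158 lower from processed signals, 23 higher and 7729 lower with median centring (0.30%), and 0 probes passed with scaling between arrays. The replicate block gave 77 probes and probes measured in both channels on all 9 arrays gave 120, against 906 with array weights, 936 from unsubtracted signals, 952 with separate channels and 1427 without the dye term. Of the 537, 192 had the same sign on all 9 arrays. Probe CUST_17310_PI427014114 was higher on 9 of 9 arrays, with a mean effect of 4.66 (limma adjusted p = 0.010), and probe CUST_44733_PI427014114 was lower on all 9, at -3.57 (limma adjusted p = 0.0022). Leaving out replicate 2 or 3 of 2 h gave 194 and 57 probes, replicate 1 or 2 of 8 h gave 145 and 92, and replicate 3 of 12 h gave 214.

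The calls at 2 h and 8 h shared 42 higher and 36 lower probes, and 9 probes were called in opposite directions. Independent lists of these sizes would share 7.05 and 4.41. The 78 calls shared in the same direction became 21 from processed signals and 264 without the dye term. A simulation of unchanged probes through the same fit called 0 probes at 2 h and 0 at 8 h, so its 0 shared calls are no measure for lists of this size. The fitted effects at the 2 times correlated at 0.25 across probes, against 0.13 in the simulation, with a covariance of 0.0750 against 0.0117. The other pairs of times differed: 2 h and 12 h correlated at 0.34 against 0.051 simulated (covariance 0.0848 against 0.00395), and 8 h and 12 h at 0.055 against 0.13 (covariance 0.0130 against 0.0125). Probes are not independent replicates, and the effects of all times use the same dye estimate.

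**Figure D3:**
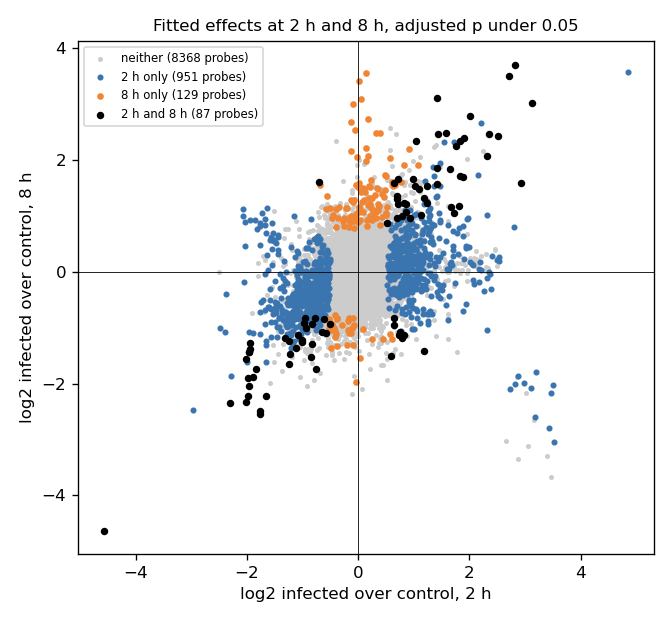
Fitted log2 ratio of infected over control skin at 2 h (x axis) and at 8 h (y axis), 1 point per probe for 9535 probes, coloured by the time at which the probe passed. Of the probes that passed at both times, 42 were higher and 36 were lower at both.

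The infection effect differed between times for 119 probes in the F test of limma, with 2319 at an unadjusted p under 0.05. This count fell to 0 with median centring, to 0 with scaling between arrays and to 0 for probes measured in both channels on all 9 arrays. It was 42 with an offset of 16, 75 without the dye term, 216 without the filter on dim probes, 236 with the robust and trended variance, 725 with array weights, 757 with separate channels, 797 from unsubtracted signals and 1192 from processed signals. Probe CUST_21062_PI427014114 was higher at 2 h, at 2.26 (SE 0.17), and stood at -0.34 at 8 h and -0.13 at 12 h, where infected signal was well above background on 1 of 3 arrays. Probe CUST_42825_PI427014114 was higher at 2 h, at 1.62 (SE 0.17), and the fit gave -0.86 at 8 h. Its infected signal was well above background on 1 of 3 arrays at 8 h and on 0 of 3 at 12 h. Probe CUST_13002_PI427014114 was higher at 8 h, at 2.55 (SE 0.24), and stood at -0.05 at 2 h, with infected signal well above background there on 2 of 3 arrays. Probe CUST_14007_PI427014114 was higher at 8 h, at 3.42 (SE 0.31), and its infected signal was not well above background on any array of 2 h. All 4 had a limma adjusted p of 0.026 for the difference. Between 8 h and 2 h the effect differed for 162 probes, 73 with a higher ratio at 8 h and 89 with a lower one (45.1% higher). From processed signals these were 155 and 46 (77.1%), and with the replicate block 142 and 74 (65.7%). Between 12 h and 2 h it differed for 67 probes, 22 higher and 45 lower at 12 h (32.8%), against 36 and 334 from processed signals (9.73%) and 54 and 69 with the replicate block (43.9%), and between 12 h and 8 h for 3. The F test gave 0 probes without replicate 2 of 2 h, replicate 1 of 8 h or replicate 2 of 8 h, 14 without replicate 1 of 2 h and 13 without replicate 2 of 12 h. It gave 237, 431 and 240 without replicate 3 of 2, 8 or 12 h. The 162 probes for 8 h against 2 h fell to 0 without replicate 2 of 2 h, replicate 1 of 8 h or replicate 2 of 8 h. They became 16 without replicate 1 of 2 h and 402 without replicate 3 of 8 h. With median centring and with scaling between arrays they fell to 0.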

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

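The tests of dye, spike-in signal, repeat classes, bacterial sequence and the second-slide array were chosen after the result they bear on was seen. The test of compressed ratios and the counts of other splits were set before.

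The infection effect differed between times for 119 probes, tested by the interaction of infection and time. Among 100 splits of the 9 arrays into times, 2 gave as many, the real one included, with 137 as the highest other. Other splits could place both swapped arrays at the same time, unlike the real layout. The share is under 0.05, but splits of unlike dye layout do not exclude chance. Pairs of times gave 162 probes for 8 h against 2 h, 67 for 12 h against 2 h and 3 for 12 h against 8 h. Leaving out 1 array moved these counts to between 0 and 402, 0 and 334, and 0 and 258. Each pair allows 10 splits, too few for a share under 0.05. The highest other counts were 0, 72 and 10. The probes CUST_21062_PI427014114, CUST_14007_PI427014114, CUST_13002_PI427014114 and CUST_42825_PI427014114 each differed between times with a limma adjusted p of 0.026.

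The other counts were set against other splits too. The 1038 probes at 2 h and the 216 at 8 h compare with a highest other count of 0, and the 0 at 12 h with 19. Each has 4 splits (values 1, 1 and 4), too few for a share under 0.05. For the mean of the 3 times, 2 of 98 splits gave as many as the real 537, the real one included, with 775 as the highest other, and 2 more could not be fitted. These splits turned the sign of arrays and so changed which ones counted as swapped. The share is under 0.05, but splits of unlike dye layout do not exclude chance.

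No probe passed at 12 h, where 3099 of the 9535 tested were well above background in both channels on all 3 arrays. Without replicate 3, which was both the swapped array and the only one on its slide, 140 passed, so that array may account for part of the gap. Its dye, its slide and its fish could not be separated, and leaving it out also removes the only check on dye at 12 h. Of the 140, 88 were higher and 52 lower. Leaving out replicate 3 of 2 h, the other swapped array, gave 40 at 12 h, all higher, so the dye estimate that rests on the swapped arrays also stays open. Compression of ratios by the low infected signal was tested on the 1038 probes called at 2 h. The median 12 h effect as a share of the 2 h effect was 0.0896 for the 314 above background on all arrays and 0.0823 for the other 724. The difference of 0.00736 has a 95% bootstrap interval over probes from -0.0331 to 0.0530, which decides neither way. The comparison would miss a compression that both sets of probes share on 1 array. On replicate 2 of 12 h, infected RNA gave 3819 probes well above background. Of probes called at 2 h, CUST_44733_PI427014114 and CUST_35760_PI427014114 lay at -0.19 and 0.06 on that array. CUST_17310_PI427014114 and CUST_17488_PI427014114 stood at 4.16 and 5.18 on it. A weaker response at 12 h also stays open.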

How the results depend on the processing

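Counts of calls depended strongly on the processing. With the main settings, calls numbered 1038 at 2 h, 216 at 8 h, 0 at 12 h, 537 for the mean, 119 in the F test, 162 for 8 h against 2 h, 67 for 12 h against 2 h and 3 for 12 h against 8 h. The 2 h and 8 h overlap held 78 and the dye effect 43. Counts that moved by over 1.5 times follow, and the cause was not tested except where fewer probes or arrays entered. No dye term gave 1285 for 8 h, 1427 for the mean, 75 for the F test, 16 for 12 h against 2 h, 10 for 12 h against 8 h and 264 for the 2 h and 8 h overlap. Only the 3 arrays of the time, no dye term gave 501 for 2 h and 1536 for 8 h. Replicate block gave 37 for 8 h, 77 for the mean, 123 for 12 h against 2 h and 11 for 12 h against 8 h. Agilent processed signals, no loess gave 581 for 2 h, 63 for 8 h, 1974 for 12 h, 1192 for the F test, 370 for 12 h against 2 h, 1785 for 12 h against 8 h, 21 for the 2 h and 8 h overlap and 524 for the dye effect. Authors' value table gave 581 for 2 h, 63 for 8 h, 1974 for 12 h, 1192 for the F test, 370 for 12 h against 2 h and 1785 for 12 h against 8 h. No background subtraction, then loess gave 434 for 8 h, 352 for 12 h, 936 for the mean, 797 for the F test, 351 for 8 h against 2 h, 822 for 12 h against 8 h and 653 for the dye effect. Normexp offset 16 gave 107 for 8 h, 42 for the F test, 99 for 8 h against 2 h, 28 for 12 h against 2 h and 1 for 12 h against 8 h. Median centring gave 2540 for 2 h, 0 for 8 h, 8862 for 12 h, 7752 for the mean, 0 for the F test, 0 for 8 h against 2 h, 0 for 12 h against 2 h, 0 for 12 h against 8 h and 9272 for the dye effect. Scale between arrays gave 202 for 2 h, 0 for 8 h, 0 for the mean, 0 for the F test, 0 for 8 h against 2 h, 0 for 12 h against 2 h and 0 for 12 h against 8 h. Separate-channel fit gave 1680 for 2 h, 516 for 8 h, 47 for 12 h, 952 for the mean, 757 for the F test, 591 for 8 h against 2 h, 378 for 12 h against 2 h and 63 for 12 h against 8 h. No filter on dim probes gave 376 for 8 h, 216 for the F test and 141 for 12 h against 2 h. Both channels on all 9 arrays gave 218 for 2 h, 29 for 8 h, 120 for the mean, 0 for the F test, 17 for 8 h against 2 h, 0 for 12 h against 2 h and 0 for 12 h against 8 h. EBayes robust and trend gave 236 for the F test, 418 for 8 h against 2 h, 174 for 12 h against 2 h and 0 for 12 h against 8 h. Array weights gave 1197 for 8 h, 6 for 12 h, 906 for the mean, 725 for the F test, 788 for 8 h against 2 h, 253 for 12 h against 2 h and 218 for 12 h against 8 h. Adjusted p under 0.10 gave 1890 for 2 h, 797 for 8 h, 1 for 12 h, 1133 for the mean, 705 for the F test, 707 for 8 h against 2 h, 315 for 12 h against 2 h, 20 for 12 h against 8 h and 298 for the 2 h and 8 h overlap. Unadjusted p under 0.05 and 1.5-fold gave 1722 for 2 h, 1595 for 8 h, 552 for 12 h, 1801 for 8 h against 2 h, 1401 for 12 h against 2 h and 1625 for 12 h against 8 h. For the F test no fold threshold applied, and 2319 had an unadjusted p under 0.05. Either RNA above background gave 111 for 12 h against 2 h. Without dinucleotide repeat probes gave 121 for 12 h against 2 h. Without the 12 h arrays gave 1560 for 2 h and 94 for 8 h. The alternatives with either RNA, without repeat probes, with 1 probe per sequence group and without the 12 h arrays were chosen after seeing the data, as was each alternative for 12 h against 8 h. Leaving out each array in turn gave 89 to 1588 for 2 h, 0 to 259 for 8 h, 0 to 140 for 12 h, 57 to 721 for the mean, 0 to 431 for the F test, 0 to 402 for 8 h against 2 h, 0 to 334 for 12 h against 2 h, 0 to 258 for 12 h against 8 h and 0 to 248 for the dye effect.

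Median centring moved the median of all probes to -0.96 at 2 h, -0.33 at 8 h and -1.61 at 12 h, and 0.63% of calls at 2 h were then higher. Processed signals moved it to 0.19 at 8 h and -0.47 at 12 h, with 92.1% and 25.3% of calls higher. Scale normalization left 69.8% of calls at 2 h higher, against 46.0% with the main settings. It also put CUST_2634_PI427014114 at 25.9 at 12 h, where its highest ratio before scaling was 4.47. Calls lost under scaling therefore need not mean weak effects. Whether the replicate numbers pair the arrays was not settled, and the replicate block gave 763 calls at 2 h. Among the alternatives for named probes, 200 kept direction and side of the threshold, 47 lost the call and 23 gained one. One turned: CUST_2634_PI427014114 at 12 h, to -1.49 under median centring. The alternatives for gene lists were not run, since no probe has a gene name, nor was the mean over a gene's probes. At 12 h, infected RNA gave 3819 to 14041 probes well above background per array.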

Other observations

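The tests of control skin between times were planned before the data were examined, and all others in this part were chosen after the results were seen. Probes of the same sequence agreed: over 330 pairs, fitted effects correlated at 0.96 across pairs at 2 h and 0.93 at 8 h. Of 50 pairs with a call at 2 h, 26 were called for both members in the same direction and 0 in opposite directions. By sequence similarity, the 9535 probes formed 8280 groups, and the 1038 calls at 2 h fell in 916 of them. In control skin, no probe differed between any 2 times in the separate-channel fit of limma, where 9, 136 and 194 of 9412 had an unadjusted p under 0.05. Chance alone would give about 470.6, so this fit was conservative and its 0 does not show that control skin stayed the same. It gave 0 also with quantile normalization (2, 62 and 79 under 0.05) and without the dye term (12, 102 and 161).

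On each of the 7 unswapped arrays, infected RNA in Cy5 gave fewer probes well above background than control RNA in Cy3, at 3819 to 12441 against 23045 to 26964. This pattern was worded first for signal in general, then for green alone and then for the unswapped arrays, each time after the test had been seen. The swapped arrays test whether dye is the whole cause. In green, 14248 and 16109 spots were well above background there for infected RNA, against 23270 to 27214 for control RNA on the other 7 (exact permutation test, two-sided, p = 0.0278, the smallest that 36 arrangements allow). Dye as the whole cause would leave green alike in both, so the green values argue against it, on 2 swapped arrays. The swapped array of 12 h lay alone on the second slide, so its counts could not be separated from the slide. The swapped array of 2 h shared a slide with the other arrays of 2 h. It had 16109 green spots against 23270 and 26016. Dye did matter: within the 2 swapped arrays, infected RNA in Cy3 gave more probes well above background than control RNA in Cy5, at 15916 against 11914 and 14041 against 8213. In red the ranges overlapped, with 8395 and 12106 for control RNA and 3913 to 12641 for infected RNA (exact permutation p = 0.611). That test ignored time, and no 8 h array was swapped. Within a time, red was higher for control than for infected RNA, at 12106 against 8565 and 9257 at 2 h and 8395 against 4175 and 3913 at 12 h. Red thus went the same way as green there, on 1 swapped array per time, with that of 12 h on the other slide. The amount or quality of the infected RNA may be a cause, and it was not told apart from a change in the skin. The median signal of the spike-in probes was at most 1.096 times that of the negative controls. Brighter spike-in probes were not examined singly, so no external scale was set.

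Probe CUST_17310_PI427014114 and the median of the 26 probes with a GA repeat of at least 6 units had ratios above 0 on all 9 arrays. Of these 26, 24 were above 0 on every array, and 7 were called at 2 h, 0 at 8 h and 0 at 12 h. The median lay between 0.71 and 5.39, and on the swapped arrays it was at least 0.743. The probe and the class were picked for staying above 0 on all 9 arrays, so that value is no test of a dye difference. Whether low-complexity sequence in general contributes was tested in 2 forms, which differed. In the first form, the predicted medians above 0 on all 9 arrays were not met: GT and TC were above 0 on 7 of 9 arrays and CA on 9. The outcome that would speak against the explanation, medians of GT, CA and TC all below 0 on every array, was not met either. This form therefore decides neither way. GT fell to -0.18 and -0.6429 on the swapped arrays, and TC to -0.05 and -0.13 on 2 arrays of 8 h. These medians mix dye with infection, and a second form was written after that outcome was seen. In it, with the dye term, the median fitted effects over the 3 times were 1.54 for GA, 0.47 for GT, 0.34 for CA and 0.247 for TC repeats, each with a 95% bootstrap interval above 0. These intervals resampled the probes of a class on the same 9 arrays, so they leave out the spread between arrays. For GT the interval was 0.446 to 0.491, while its medians per array ran from -0.643 to 3.55. Of the GT, CA and TC probes, 3 of 86, 8 of 36 and 1 of 21 were above 0 on all arrays, and 0 were called at 2, 8 or 12 h. The explanation stays open. Under median centring the median of all probes lay at -0.98, and GA, GT, CA and TC lay 1.61, 0.20, 0.41 and 0.27 above it. One hypothesis for CUST_17310_PI427014114 is bacterial ribosomal RNA. It holds a stretch recalled from memory as conserved in bacterial 16S rRNA, but that stretch was picked after the probe was seen, so the match is no evidence on its own. Of all 50979 probes, 0 held any of 6 further recalled stretches on either strand, so that search could not test the hypothesis. With no bacterial reference used here the source cannot be told.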
